A study of Homo sapiens with 12 samples.

How the data were processed

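RNA was sequenced in 12 libraries of MV4-11 cells, 3 for each of DMSO (0.1%), BSJ-03-123, YKL-06-102 and palbociclib (each at 200 nM for 6 h), after polyadenylated RNA selection with a TruSeq Stranded mRNA kit, per the labels' protocols. The deposited table holds raw read counts per Ensembl gene and library, with no normalization. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned to hg38 with STAR 2.5.2b and counted with HTSeq. The annotation release, the strand setting of the counting and the HTSeq version are not given in the sources used here. Every value in the table was a whole number, and all 12 columns were mapped to a labelled library. How the replicates relate (separate cultures, or repeats of a culture) and the days or batches of the libraries are not given in the labels.

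Gene IDs were matched to GENCODE 29 (GRCh38), which named 57447 of 58051 and gave coordinates, strand, transcript length and GC content, and 604 IDs had no name. Of 28826 genes with a count in any library, 14214 passed edgeR's filterByExpr with the 4 groups (minimum count 10, minimum total count 15). They held 99.9% of all counts, and 51 of them had no symbol. Library totals ranged from 18764307 to 25539858. CPM were computed with edgeR's TMM factors, and group values are the mean and SD of CPM over 3 libraries.

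All 12 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test, 8 residual degrees of freedom, prior count 0.125), and the 6 contrasts between groups were tested 2-sided. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of the contrast. Standard errors and 95% intervals of log2 fold changes are Wald values from that fit. The common biological coefficient of variation was 3.08%. Replicate pairs were compared with a chi-square statistic on counts, per degree of freedom, where 1 is sampling noise alone. Principal components were computed on log2 CPM of the tested genes with a mean log2 CPM of at least 2. A count of 0 in a library allows up to 3 counts, and intervals of counting cover counting error only, since reads had no molecular identifiers.

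The tests were checked on simulated data first: counts for the real genes were drawn from the DMSO means and real library sizes, with 200 genes changed. The changed genes were picked among those with a DMSO mean of at least 4 CPM, so the shares called do not cover weaker genes. For YKL-06-102 against DMSO, 84% of the genes changed 1.25-fold were called, as were 98% of those changed 1.5-fold and 100% of those changed 2-fold or 3-fold, among 13953 tested genes. For BSJ-03-123 against palbociclib the shares were 88%, 98%, 100% and 100% among 13950 genes. Unchanged genes were called 10 times in the first comparison, 4.98% of its calls, and 18 times in the second, 8.53%, in 1 draw each. The 95% intervals held the true value for 95.2% of genes in the first comparison.

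Before the data were examined, 22 gene lists were written from general knowledge: E2F and G1/S genes, G2/M and mitosis genes, the cyclin D, CDK4/6, RB and E2F module, genes described as regulated by CDK6 as a transcriptional cofactor, KMT2A fusion targets, myeloid differentiation, p53 targets, MYC and ribosome biogenesis, interferon genes, MAPK and immediate-early genes, FLT3 and STAT5 targets, integrated stress response, cholesterol and SREBP targets, lysosome and TFEB genes, NF-kappaB and cytokines, the BCL2 family, cereblon with its ligase genes and reported substrates, replication-dependent histones, lymphoid, erythroid and megakaryocyte, and stromal and epithelial markers, and mitochondrially encoded genes. Each list with at least 5 tested members was tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01. Benjamini-Hochberg adjustment was over the lists of a contrast. Camera with an estimated correlation and fry were also run. Fry is given for the G2/M list, and for the stromal and epithelial markers and some further lists. These others were picked for it after its results were seen. Some genes belong to more than 1 list. Counts of called members are given over all tested genes and adjusted over the list alone.

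The rule for named genes was also fixed before the data were examined. Against DMSO it takes, among called genes with an average log2 CPM of at least 2 whose 3 treated libraries lay all above or all below the 3 DMSO libraries, the 8 highest and 8 lowest log2 fold changes. Between compounds it takes the 5 highest and 5 lowest by the same criteria. It adds up to 3 called members of each list by smallest p, CDK4, CDK6, CCND2, CCND3, CCNE1, CCNE2, E2F1, RB1, CDKN1A and MYC in every contrast, and any member of the CDK-RB and CDK6 cofactor lists. Not every gene the rule allows is named. Values of a gene named by the rule in 1 contrast are also given in others for comparison.

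Similarity of responses was measured over the 14214 genes by the covariance and Pearson r of log2 fold changes and by shared calls. Because the 3 DMSO libraries serve every contrast with DMSO, the same values were computed for simulated unchanged groups over 20 draws. The DMSO libraries were simulated too and shared by the contrasts in the same way. Shared calls are given beside the number that independent lists of the same sizes would share.

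The counts of called genes, the E2F and G2/M lists and the named genes were recomputed with RLE size factors, with library totals alone, with no filter on low counts, with a filter of at least 1 CPM in at least 3 libraries, with DESeq2 1.42.0, with limma-voom, with the 2 compared groups only, with the replicate number as a block and without each library in turn. Chosen after the data were seen, further runs were made with each library's trend on GC content or on transcript length removed through the offsets, and with counts thinned to the smallest library. GC content and length were known for 99.6% of the tested genes. For each contrast all 10 splits of its 6 libraries into 3 and 3 were tested in the same way. No library was left out of the values in the report.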

Results

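Gene expression was measured by polyadenylated RNA sequencing in MV4-11 cells, a human acute myeloid leukaemia line that carries a KMT2A fusion and an internal tandem duplication of FLT3. Cells had been treated for 6 h with 200 nM palbociclib, BSJ-03-123 or YKL-06-102, or with the vehicle, 0.1% DMSO, and each of the 4 groups had 3 libraries. Palbociclib is a catalytic inhibitor of the kinases CDK4 and CDK6. The submitters describe BSJ-03-123 and YKL-06-102 as CDK6-specific conjugates in a study of selective CDK6 degradation, and the labels name no structural difference between them. The deposited table of raw read counts held 58051 genes, of which 14214 were tested, and library totals ranged from 18764307 to 25539858 counts. They lay between 18764307 and 25539858 for DMSO, 19803323 and 21021137 for BSJ-03-123, 23416204 and 24350966 for YKL-06-102 and 20565788 and 24289426 for palbociclib. Every pair of replicates differed by more than sampling noise. DMSO replicate 2 stood farthest from its group, with chi-square values per degree of freedom of 5.41 and 8.18 against the other DMSO libraries, where no other pair exceeded 2.76. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. On principal components of log2 CPM, the counts scaled by library size, the first component, with 51.2% of the variance, separated DMSO from the 3 compounds, and the second, with 28.4%, separated YKL-06-102 from the other groups. The sources do not say whether strand was used in counting, so the counts of genes that overlap an expressed gene are uncertain, among the genes named here CCNE2, CHAF1B, FADS2, GINS2, TMEM150A and PPP1R13L, whose overlapping partner had more counts, and CCNA2, CDK4, CDK6, DNAJA4, FADS1, FOXM1, FRMD4A, HELLS, MCM2, NOP56, RB1, SLC1A5, TYMS and BCL2L2. Values after a log2 fold change are standard errors (SE) from the edgeR quasi-likelihood fit, values after a CPM are SDs, and n = 3 libraries per group throughout.

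The effect of catalytic CDK4/6 inhibition was read from palbociclib against DMSO, where genes of DNA replication fell. All 72 genes of the E2F and G1/S list fell, with a median log2 fold change of -1.51, or 2.85 times lower. The lowest was CCNE2, cyclin E2, which drives S-phase entry with CDK2: it went from 45.6 ± 3.16 CPM to 1.95 ± 0.446 CPM (log2 fold change -4.56 ± 0.14). Other large decreases were those of WDR76 (-2.70 ± 0.062), UNG, which removes uracil from DNA (-2.67 ± 0.052), GINS2 and CDC45 of the replicative helicase (-2.60 ± 0.068 and -2.37 ± 0.051), the histone chaperone subunit CHAF1B (-2.42 ± 0.067) and the transcription factor E2F1 (-2.53 ± 0.054). The helicase subunits MCM2, MCM3 and MCM4 changed by -2.09, -1.78 and -2.18, MCM4 from 1009 ± 16.7 to 222 ± 2.91 CPM. CCNE2 is annotated in GRCh38 as ENSG00000175305, chromosome 8, 94879770 to 94896678, and E2F1 as ENSG00000101412, chromosome 20, 33675683 to 33686404.

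In the G2/M and mitosis list 62 of 64 genes fell with palbociclib, with a median of -0.44. They included the mitotic cyclin CCNA2 (-0.74 ± 0.033), the transcription factor FOXM1 (-0.84 ± 0.038) and the kinase MELK (-1.17 ± 0.054). Of the 25 tested genes of the cyclin D, CDK4/6, RB and E2F module, 15 fell and 3 rose, and the members that fell included CDK2 (-1.48 ± 0.048), E2F8 (-1.88 ± 0.064), RBL1 (-1.44 ± 0.049) and the CDK4/6 inhibitor CDKN2C (-0.85 ± 0.048). The increases were smaller: the largest among genes of average log2 CPM of 2 or more were those of TMEM150A (0.97 ± 0.084), the kinase DYRK1B (0.94 ± 0.073) and MXD4, a partner of MAX that opposes MYC (0.93 ± 0.049). Monocyte and granulocyte differentiation genes rose in 15 of 36 cases, among them CSF1R, the receptor of macrophage colony-stimulating factor (0.51 ± 0.040), and TLR2 (0.27 ± 0.048), and the other 21 did not pass the test. Single members of other lists fell too: the transporter SLC1A5 (-0.46 ± 0.040), the desaturase FADS1 (-0.67 ± 0.031), the nucleolar protein NOP56 (-0.31 ± 0.028) and the p53 target DDB2 (-0.71 ± 0.061).

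E2F1, E2F2, E2F7, E2F8 and RBL1 are members of both the E2F and the CDK-RB list. In total 2224 genes were higher and 2507 lower with palbociclib than with DMSO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), of which 39 and 223 changed at least 2-fold. By camera, the E2F and G1/S list (adjusted p = 3.10e-08 with an estimated correlation), the G2/M list (5.01e-04), the CDK-RB module (6.06e-04) and the myeloid list (0.0325) were called, also with the preset correlation. Adjusted over the list alone, 72 of 72, 62 of 64, 15 of 25 members of the first 3 lists fell and 15 of 36 myeloid members rose. With library totals in place of TMM factors, 3396 genes were higher and 1949 lower, and without DMSO replicate 2 the count was 4599 genes.

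**Figure D1:**
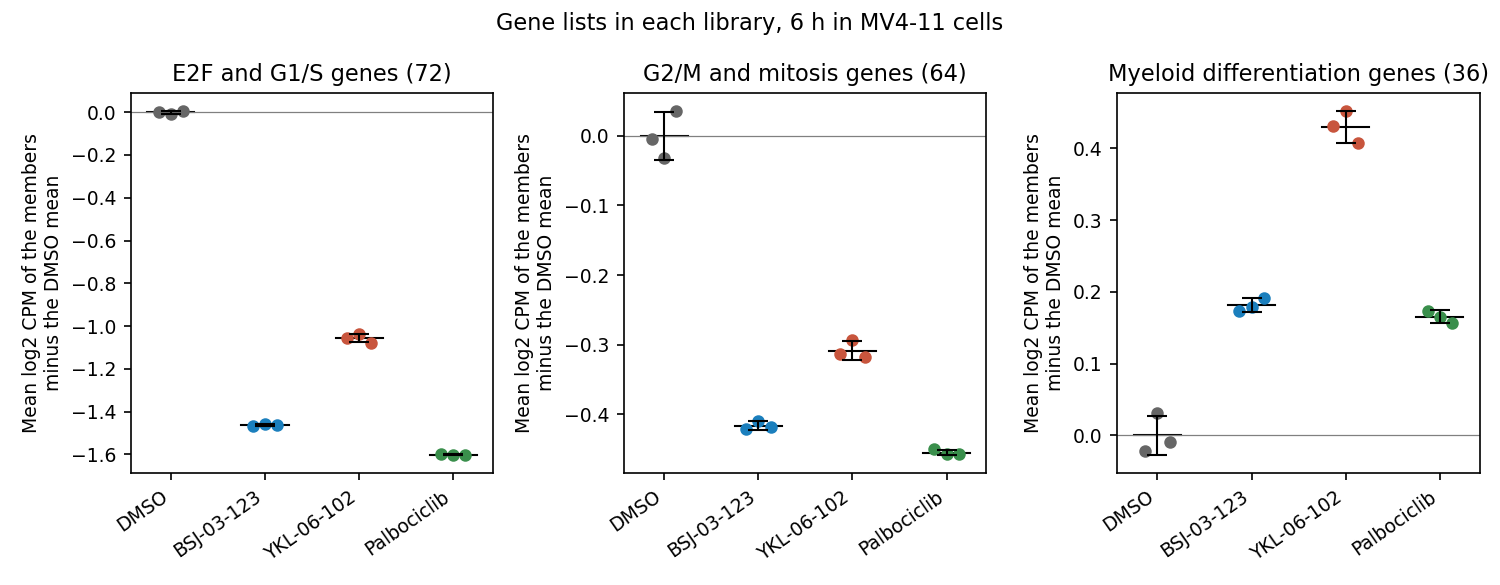
Mean log2 CPM of the members of 3 gene lists in each of the 12 libraries, minus the mean of the 3 DMSO libraries (points, libraries; bars, group mean ± SD, n = 3). The E2F and G1/S score lay at -1.60 with palbociclib, -1.46 with BSJ-03-123 and -1.06 with YKL-06-102, and the myeloid score was highest with YKL-06-102.

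BSJ-03-123 against DMSO asked what the first conjugate did at the same dose and time. The E2F and G1/S list again fell in full, 72 of 72 genes, with a median log2 fold change of -1.40, or 2.64 times lower. CCNE2 fell to 3.45 ± 0.531 CPM (-3.72 ± 0.12), UNG changed by -2.54, GINS2 by -2.42, E2F1 by -2.40, CHAF1B by -2.34, WDR76 by -2.34, CDC45 by -2.24 and E2F2 by -2.24. MCM4, MCM3 and MCM2 changed by -1.94, -1.69 and -1.89. In the G2/M list 62 of 64 genes fell, with a median of -0.41, with CCNA2 at -0.66 ± 0.033, NUSAP1 at -0.64 ± 0.033 and the mitotic kinase CDK1 at -0.69 ± 0.036.

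Among genes with an average log2 CPM of 2 or more, the largest increase after BSJ-03-123 was that of IL7R, the interleukin-7 receptor alpha chain, which went from 3.38 ± 0.567 to 7.78 ± 0.141 CPM (1.21 ± 0.12). NCKAP5L (0.97 ± 0.076), TMEM150A (0.92 ± 0.086), RAB7B (0.86 ± 0.12), MXD4 (0.81 ± 0.050) and DYRK1B (0.79 ± 0.075) rose as well. Of the myeloid differentiation genes 14 of 36 rose and 22 did not pass the test, with CSF1R at 0.55 ± 0.040, FCGR2A at 0.48 ± 0.063 and TLR2 at 0.24 ± 0.049. FCGR2A has close paralogs, so its counts are uncertain. Among reported substrates of cereblon, the ubiquitin ligase adaptor that many degraders recruit, the zinc-finger gene ZNF692 rose from 86.9 ± 3.83 to 125 ± 6.87 CPM (0.52 ± 0.045), and 4 of the 20 tested genes of that list rose and 4 fell (camera adjusted p = 0.398). In the CDK-RB module 15 of 25 genes fell and 4 rose.

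With BSJ-03-123, 1763 genes were higher and 2234 lower than with DMSO, and 29 and 183 of them changed at least 2-fold. Camera called the E2F and G1/S (adjusted p = 9.28e-09 with an estimated correlation), G2/M (5.39e-04), CDK-RB (6.28e-04) and myeloid (0.0162) lists under both correlations. Adjusted over the list alone, 72, 62 and 15 members of the first 3 fell and 15 of the fourth rose. With library totals as the only scaling 2852 genes were higher and 1765 lower, and without DMSO replicate 2 the count was 4088 genes.

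YKL-06-102 lowered the same E2F and G1/S list by less and changed a set of further genes. The 72 members all fell against DMSO, with a median log2 fold change of -1.003, or 2.004 times lower. CCNE2 changed by -2.07, E2F2 by -2.38, UNG by -1.73, WDR76 by -1.63, E2F1 by -1.62, and MCM4, TYMS, the thymidylate synthase, and MCM3 by -1.25, -1.32 and -1.14. In the G2/M list 58 of 64 genes fell and 1 rose, with a median of -0.31, with CCNA2 at -0.57 ± 0.033, CDK1 at -0.61 ± 0.036 and FOXM1 at -0.53 ± 0.037.

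Increases were larger than with the other compounds. Several of the genes encode surface proteins of myeloid cells, a grouping that was not tested. The highest log2 fold change in the myeloid list was 1.73, so the genes named next with larger ones are not its members. TREM2, a lipid-sensing receptor of macrophages, rose from 2.003 ± 0.235 to 20.04 ± 0.362 CPM (3.31 ± 0.13), a 9.89-fold increase, and IL7R from 3.38 ± 0.567 to 20.8 ± 1.57 CPM (2.63 ± 0.11). The arrestin family gene ARRDC4 (2.30 ± 0.053), PPP1R13L (2.16 ± 0.10), the sialic acid receptor SIGLEC1 (2.14 ± 0.093), FRMD4A (2.08 ± 0.091), the aminopeptidase ANPEP, also known as CD13 (2.05 ± 0.14), and the neonatal Fc receptor gene FCGRT (2.01 ± 0.065) followed. TREM2 lies in GRCh38 at ENSG00000095970, chromosome 6, 41158506 to 41163186. Of the 36 myeloid differentiation genes 25 rose and 11 did not pass the test, with a median of 0.28: CSF1R went from 63.0 ± 1.93 to 144 ± 1.88 CPM (1.19 ± 0.039), FCGR2A rose by 1.58 ± 0.057 and the lipopolysaccharide receptor TLR4 by 0.94 ± 0.058. TNF (1.19 ± 0.081) and TNFAIP2 (0.75 ± 0.039) rose among 10 of 21 NF-kappaB and cytokine genes, 2 of which fell. TFE3 (0.71 ± 0.047) rose among 11 of 36 lysosome genes, 3 of which fell. ZNF692 rose from 86.9 ± 3.83 to 192 ± 10.3 CPM (1.14 ± 0.044). Among genes outside the E2F list with an average log2 CPM of 2 or more, the largest decreases were those of the zinc-finger gene C11orf95 (-2.71 ± 0.12), the cadherin CELSR2 (-2.09 ± 0.12), the kinesin light chain KLC2 (-1.79 ± 0.11) and TK2, the mitochondrial thymidine kinase, which went from 40.6 ± 2.40 to 11.7 ± 0.711 CPM (-1.78 ± 0.063).

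In this comparison 2215 genes were higher and 3034 lower, with 220 and 165 changed at least 2-fold. The E2F and G1/S (camera adjusted p = 1.27e-07 with an estimated correlation), G2/M (0.00486), CDK-RB (0.00486) and myeloid (2.86e-04) lists were called under both correlations. The NF-kappaB list was called with the preset correlation and lost with an estimated one (adjusted p = 0.0733), as were the lysosome list (adjusted p = 0.140) and the ribosome biogenesis list, where 23 of 43 genes fell and 1 rose (adjusted p = 0.0963). Adjusted over the list alone, 72 E2F, 59 G2/M and 14 CDK-RB genes fell, and 26 myeloid, 10 NF-kappaB and 11 lysosome genes rose. On the same basis 3 NF-kappaB and 3 lysosome genes fell. With library totals alone 2877 genes were higher and 2422 lower, and without DMSO replicate 2 the count was 5583 genes.

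**Figure D2:**
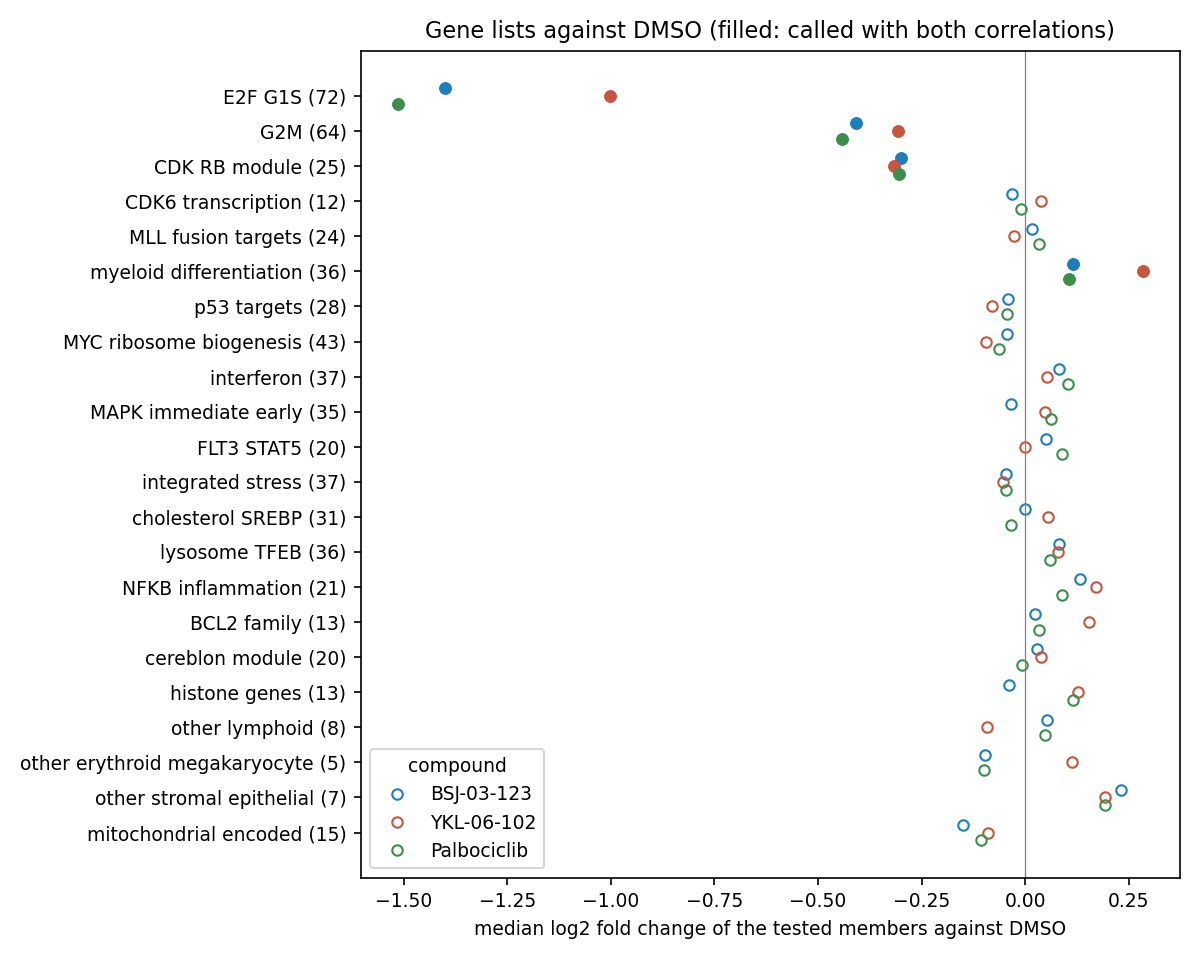
Median log2 fold change of the tested members of each of the 22 gene lists against DMSO, for the 3 compounds (numbers of tested members in brackets; filled circles, lists that camera called with the preset and with an estimated correlation). The E2F and G1/S, G2/M, CDK-RB and myeloid lists were called with every compound, and E2F medians were -1.51, -1.40 and -1.003 with palbociclib, BSJ-03-123 and YKL-06-102.

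Of the transcripts of the targeted kinases, that of CDK6 changed little and that of CDK4 fell by more, and the table does not measure protein. CDK6 was higher with each compound, from 446 ± 22.8 CPM with DMSO to 509.7 ± 13.3 with BSJ-03-123 (0.19 ± 0.035), 499 ± 12.2 with YKL-06-102 (0.16 ± 0.035) and 491 ± 10.8 with palbociclib (0.14 ± 0.035). CDK4 was lower with each, at -0.42 ± 0.033, -0.36 ± 0.033 and -0.45 ± 0.033 in the same order. The cyclin D2 gene CCND2 rose by 0.50 ± 0.048, 0.76 ± 0.046 and 0.42 ± 0.047. The cyclin D3 gene CCND3 did not pass the test with any compound (-0.0020 ± 0.041, 0.085 ± 0.040 and -0.081 ± 0.040), nor did MYC with BSJ-03-123 (-0.018 ± 0.035) or palbociclib (-0.060 ± 0.035), while with YKL-06-102 it was lower at -0.10 ± 0.035 (edgeR quasi-likelihood test, adjusted p = 0.0214). That call was lost without DMSO replicate 2 (-0.037), without any 1 of the YKL-06-102 libraries (-0.098 to -0.067) and with library totals (-0.064). CCND3 passed the test with YKL-06-102 without DMSO replicate 2 (0.17) and with palbociclib without DMSO replicate 1 or 3 (both -0.12). RB1 was lower with all 3 (-0.30 ± 0.043, -0.36 ± 0.042 and -0.24 ± 0.042), and CCNE1 changed by -1.41, -0.83 and -1.498. CDKN1A, the p21 gene, fell with BSJ-03-123 (-0.31 ± 0.050) and palbociclib (-0.32 ± 0.050), with YKL-06-102 at 0.039 ± 0.048, where the test was not passed. Between compounds, CDK6 differed by 0.054 ± 0.034 for BSJ-03-123 against palbociclib (95% interval -0.016 to 0.13), by 0.024 ± 0.034 for YKL-06-102 against palbociclib (-0.046 to 0.095) and by 0.030 ± 0.034 for BSJ-03-123 against YKL-06-102 (-0.041 to 0.10), and none of these passed the test (edgeR adjusted p = 0.717, 0.670 and 0.625). CDK6 lies in GRCh38 at ENSG00000105810, chromosome 7, 92604921 to 92836594, and CDK4 at ENSG00000135446, chromosome 12, 57747727 to 57756013. Genes that CDK6 has been described to regulate as a transcriptional cofactor, 12 tested, were called as a list by camera in no comparison (adjusted p = 0.675, 0.989 and 0.668 against DMSO). Single members did change: 1 rose and 4 fell with BSJ-03-123, 4 and 5 with YKL-06-102 and 2 and 4 with palbociclib. Fry, which tests a list without the other genes, called it lower with BSJ-03-123 (adjusted p = 0.00574) and palbociclib (0.00752). It did not with YKL-06-102 (0.322).

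**Figure D3:**
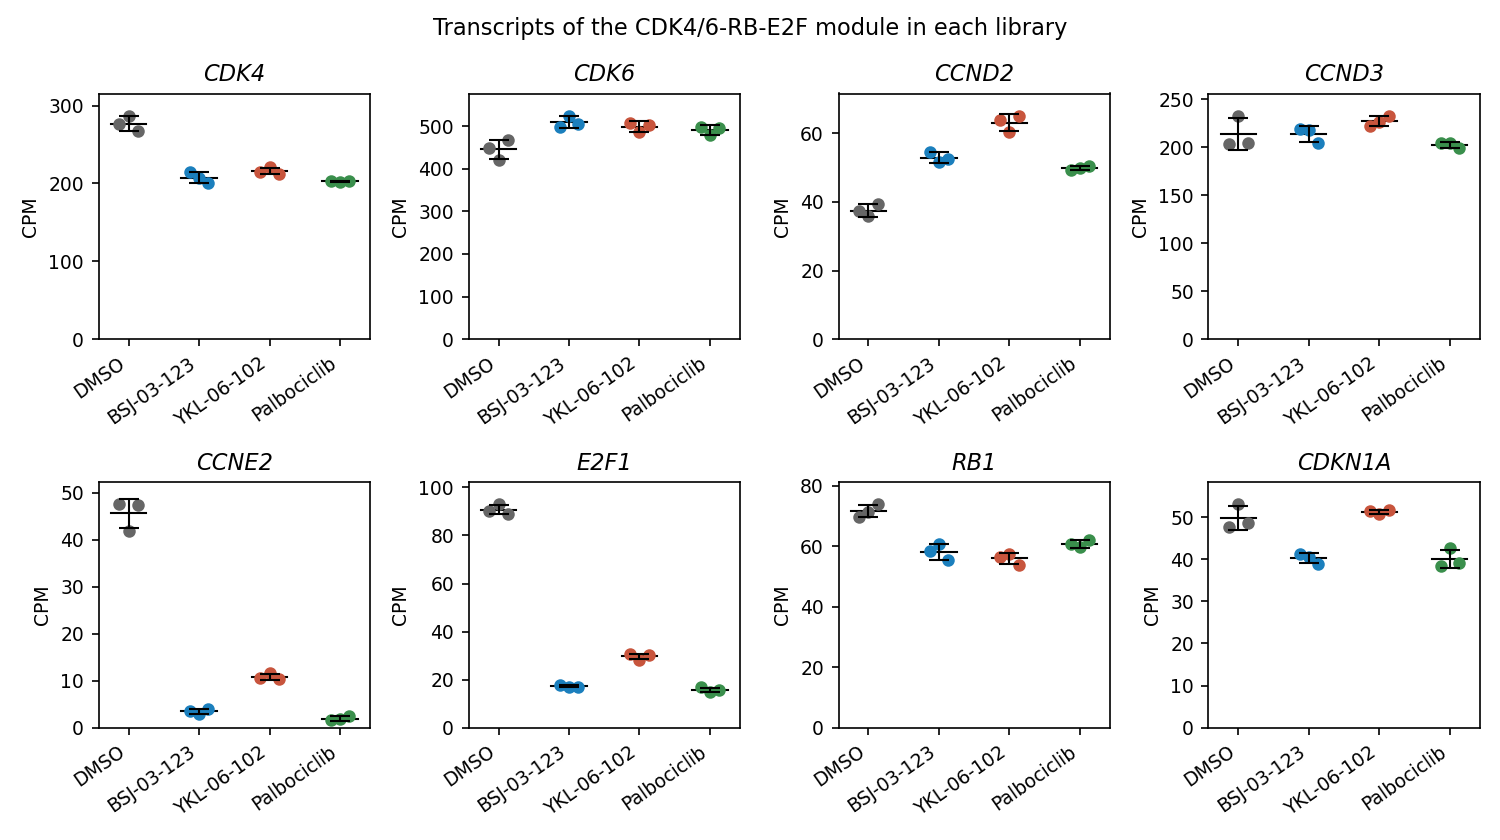
CPM of 8 transcripts of the CDK4/6, RB and E2F module in each of the 12 libraries (points, libraries; bars, group mean ± SD, n = 3; every axis starts at 0). CDK6 lay between 446 ± 22.8 CPM with DMSO and 509.7 ± 13.3 CPM with BSJ-03-123, while CCNE2 fell from 45.6 ± 3.16 CPM to 1.95 ± 0.446 CPM with palbociclib.

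Direct comparison of BSJ-03-123 with palbociclib asked whether the 2 responses differed at 200 nM and 6 h. With the filter and all 12 libraries, few genes differed: 22 were higher with BSJ-03-123 and 0 lower. ZNF692 was highest in significance, at 125 ± 6.87 CPM against 87.3 ± 2.504 CPM (0.51 ± 0.045, edgeR quasi-likelihood adjusted p = 9.10e-08), followed by the heat shock gene HSPA1A at 179 ± 10.6 against 137 ± 3.37 CPM (0.39 ± 0.042), whose near-identical copy HSPA1B makes its counts uncertain. The E2F and G1/S genes were lowered less by BSJ-03-123: 11 of 72 were higher than with palbociclib, 36 adjusted over the list alone, by a median of 0.12 (camera adjusted p = 9.95e-05 with an estimated correlation). MCM4 differed by 0.24 ± 0.031, CCNE2 by 0.84 ± 0.18, the chromatin remodeller HELLS by 0.44 ± 0.091 and IL7R by 0.63 ± 0.11. The G2/M list, with a median of 0.033, was called with the preset correlation and lost with an estimated one (adjusted p = 0.252), and the same held for the CDK-RB module (adjusted p = 0.252) and the ribosome biogenesis list (adjusted p = 0.169). The myeloid list did not pass the test (median 0.0027, camera adjusted p = 0.797).

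At an unadjusted p below 0.05, 681 genes were higher and 517 lower. DESeq2 called 38 higher and 5 lower and limma-voom 17 higher and 0 lower. With edgeR, 61 were higher and 14 lower in a fit of the 2 groups only, and 42 and 22 with no filter on low counts. GC trends removed gave 67 and 10. With all 12 libraries and without these 3 changes, none of the 3 tools called a gene at least 2-fold different. Of 10368 genes with an average log2 CPM of at least 2, 99.8% had a 95% interval of the difference within 1.5-fold. The count rested on single libraries: without palbociclib replicate 1 it was 3 genes, without replicate 2 of either group 5, and without replicate 1 or 3 of BSJ-03-123 or replicate 3 of palbociclib 14. ZNF692, HSPA1A and MCM4 were called without any 1 of the 6 libraries. IL7R was lost without BSJ-03-123 replicate 2 (0.62), palbociclib replicate 1 (0.64) or palbociclib replicate 2 (0.59), HELLS without any 1 except BSJ-03-123 replicate 1 (log2 fold changes from 0.39 to 0.46 in the runs that lost it) and CCNE2 without any 1 except palbociclib replicate 3 (0.71 to 0.95). CCNE2 and HELLS also missed the threshold with limma-voom (adjusted p = 0.0973 and 0.0826).

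YKL-06-102 against palbociclib showed a smaller decrease of the E2F genes and differences in further genes. Palbociclib had moved some of these itself: 796 of the genes higher with YKL-06-102 were called lower with palbociclib against DMSO, and 676 of the lower genes were called higher. Of the E2F and G1/S genes 70 of 72 were higher with YKL-06-102, 71 adjusted over the list alone, by a median of 0.49 (camera adjusted p = 4.13e-06 with an estimated correlation): MCM4 stood at 423 ± 5.33 CPM against 222 ± 2.91 CPM (0.93 ± 0.030), CCNE2 differed by 2.49 ± 0.15, TCF19 by 1.33 ± 0.054 and MCM2 by 0.87 ± 0.037. In the CDK-RB module 12 of 25 genes were higher and 2 lower, with E2F1 at 0.91 ± 0.058 and CDK2 at 0.69 ± 0.050 (list adjusted p = 0.0295 with an estimated correlation). E2F2 was an exception within the E2F list, at -0.11 ± 0.100, where the test was not passed. Among genes outside the E2F list with an average log2 CPM of 2 or more, TREM2 (2.85 ± 0.11), CTDSPL, a small phosphatase that acts on RB (2.38 ± 0.14), PPP1R13L (2.35 ± 0.10) and IL7R (2.05 ± 0.095) were the most increased, and C11orf95 (-2.71 ± 0.12), TK2 (-1.97 ± 0.062), the retinoic acid receptor RARG (-1.91 ± 0.12), CELSR2 (-1.91 ± 0.12) and UBASH3B (-1.78 ± 0.100) the most decreased. Myeloid differentiation genes were higher in 17 of 36 cases and lower in 3 (median 0.17, camera adjusted p = 0.00212 with an estimated correlation), with FCGR2A at 1.31 ± 0.054, TLR4 at 0.89 ± 0.057 and CSF1R at 0.69 ± 0.037. Cholesterol and SREBP target genes were higher in 17 of 31 cases, led by the desaturases FADS1 (0.72 ± 0.031), FADS2 (0.61 ± 0.038) and SCD (0.27 ± 0.031), and lower in 2, a call that was lost with an estimated correlation (adjusted p = 0.0612). ZNF692 differed by 1.13 ± 0.043 and IKZF1, the gene of a lymphoid transcription factor that cereblon ligands target, by 0.31 ± 0.033. The pro-survival gene BCL2 was lower (-0.20 ± 0.033) and its relative BCL2L2 higher (0.60 ± 0.059).

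**Figure D4:**
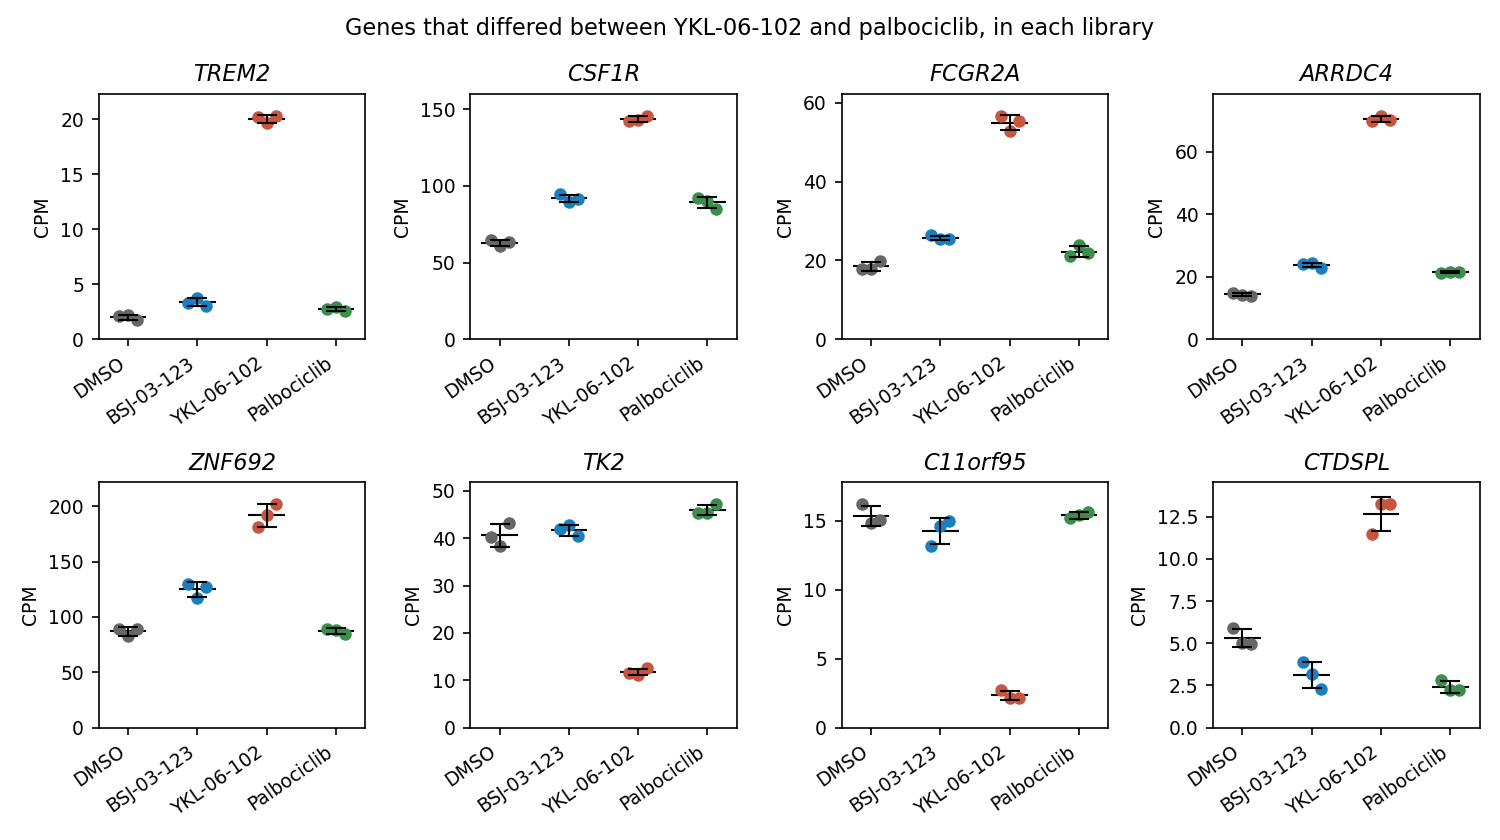
CPM of 8 genes that differed between YKL-06-102 and palbociclib in each of the 12 libraries (points, libraries; bars, group mean ± SD, n = 3; every axis starts at 0). TREM2 stood at 20.04 ± 0.362 CPM with YKL-06-102 and 2.77 ± 0.179 CPM with palbociclib, and TK2 at 11.7 ± 0.711 and 46.0 ± 1.01 CPM.

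Altogether 1812 genes were higher and 1695 lower with YKL-06-102 than with palbociclib (edgeR quasi-likelihood test), and 161 and 65 differed at least 2-fold. The lower count was 1057, 1054 and 1031 without YKL-06-102 replicate 1, 2 or 3, 985 and 1052 without palbociclib replicate 1 or 2 and 1103 with DESeq2. With library totals 1689 genes were higher and 1894 lower. The G2/M list, with 33 of 64 genes higher, was lost with an estimated correlation (adjusted p = 0.0612).

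The 2 conjugates also differed from each other. With BSJ-03-123, 68 of the 72 E2F and G1/S genes were lower than with YKL-06-102, 69 adjusted over the list alone, by a median of -0.37 (camera adjusted p = 1.29e-05 with an estimated correlation), with MCM4 at -0.68 ± 0.030, TCF19 at -1.04 ± 0.053, E2F1 at -0.79 ± 0.058 and CCNE2 at -1.65 ± 0.13. Myeloid genes were lower in 15 of 36 cases and higher in 2 (camera adjusted p = 0.00112 with an estimated correlation), among them FCGR2A (-1.09 ± 0.053), TLR4 (-0.78 ± 0.057) and CSF1R (-0.64 ± 0.037). Among genes with an average log2 CPM of 2 or more, TREM2 (-2.57 ± 0.11), PPP1R13L (-2.37 ± 0.11), CTDSPL (-2.02 ± 0.14), FCGRT (-1.80 ± 0.062) and SIGLEC1 (-1.80 ± 0.087) were the most decreased relative to YKL-06-102, and C11orf95 (2.60 ± 0.12), TK2 (1.83 ± 0.063), UBASH3B (1.68 ± 0.10), the immune GTPase gene GIMAP1 (1.66 ± 0.15) and CELSR2 (1.65 ± 0.13) the most increased. ZNF692 was lower with BSJ-03-123 (-0.62 ± 0.042), as were FADS1 (-0.55 ± 0.031) and CDKN1A (-0.35 ± 0.049). In all, 1385 genes were higher and 1476 lower with BSJ-03-123 than with YKL-06-102, 169 of them at least 2-fold. The higher count was 903 without BSJ-03-123 replicate 1 and 840, 823 and 795 without YKL-06-102 replicate 1, 2 or 3. With library totals 1464 genes were higher and 1397 lower. The G2/M (adjusted p = 0.139), CDK-RB (0.0677), cholesterol (0.110) and ribosome biogenesis (0.159) lists were called with the preset correlation and lost with an estimated one.

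Across the 3 comparisons with DMSO, palbociclib lowered most E2F genes most and YKL-06-102 least: in 69 of the 72 genes the order was palbociclib, BSJ-03-123, YKL-06-102, and the median effect was 91.4% of that of palbociclib with BSJ-03-123 and 66.3% with YKL-06-102. Over all 14214 genes, log2 fold changes of BSJ-03-123 and palbociclib had a Pearson r of 0.865, those of BSJ-03-123 and YKL-06-102 0.661, and those of YKL-06-102 and palbociclib 0.609. Genes are not independent replicates, and the 3 DMSO libraries, too few to split, are shared. Simulated unchanged groups, with simulated DMSO libraries shared in the same way, gave r of 0.513, 0.514 and 0.528. The draws used the joint spread of all groups, so they do not carry the larger distance of DMSO replicate 2. Simulated values may therefore be too low. The covariance was 0.0929 for BSJ-03-123 and palbociclib against 0.0146 simulated, 0.0793 against 0.0145 for the 2 conjugates and 0.0786 against 0.0146 for YKL-06-102 and palbociclib. BSJ-03-123 and palbociclib shared 1407 higher and 2003 lower genes, where independent lists of those sizes would share 276 and 394 and the simulation gave 0.100 and 0.05 on average. Independent lists leave out the shared DMSO libraries, and the simulated groups held no changed genes. Neither value therefore shows how many shared calls these libraries add where many genes change. YKL-06-102 and palbociclib shared 1088 higher and 1878 lower genes (347 and 535 for independent lists), and 171 genes were called in opposite directions by those 2, each of them also called in the direct comparison.

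**Figure D5:**
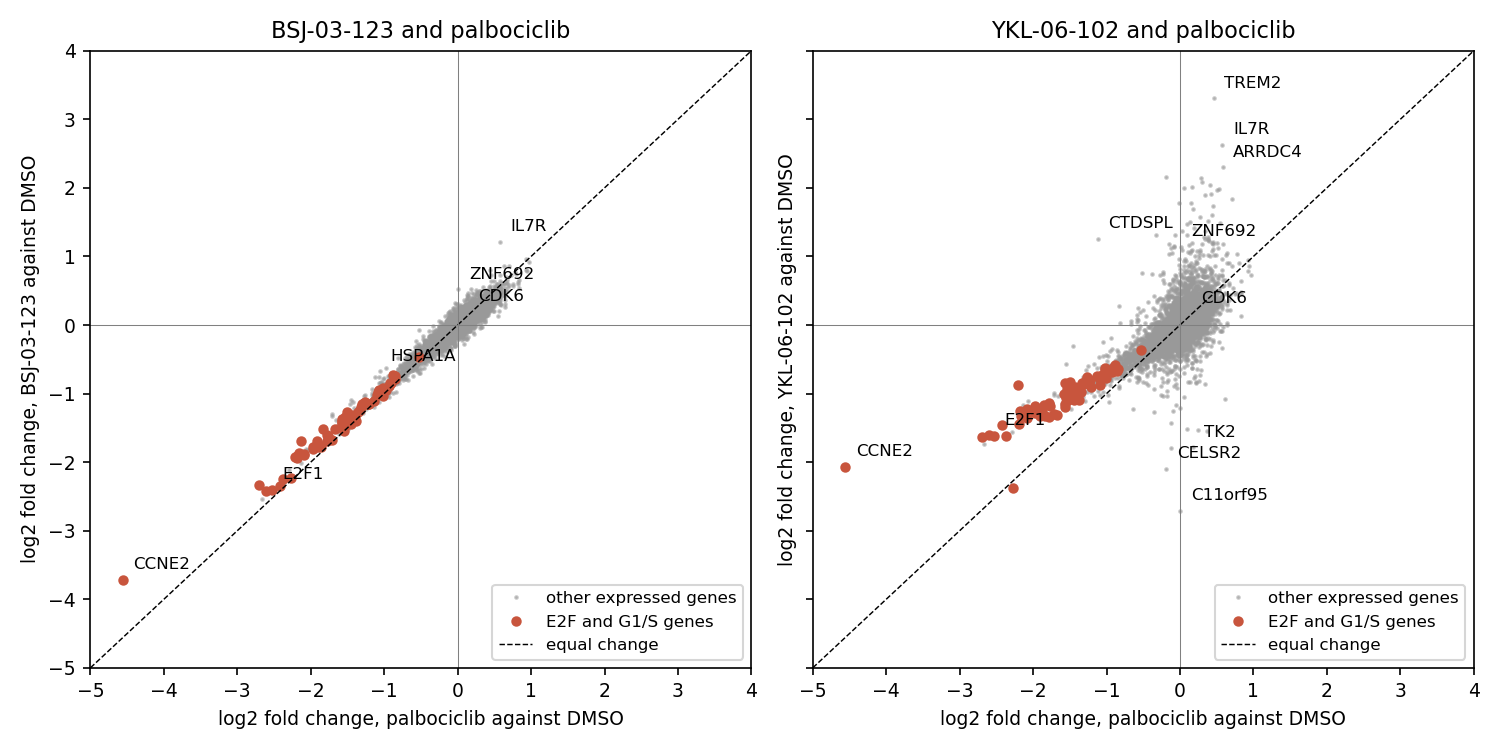
Log2 fold change against DMSO of each gene with an average log2 CPM of at least 2, for BSJ-03-123 (left) and YKL-06-102 (right) on the vertical axis and palbociclib on the horizontal axis (red, the 72 E2F and G1/S genes; dashed, equal change). Points of the left panel lie near the line of equal change, while E2F genes of the right panel lie above it and genes such as TREM2 and C11orf95 lie far from the horizontal axis at little change with palbociclib.

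The remaining lists fixed before the data were examined gave no call of camera against DMSO with any compound, and neither did the markers of other cell types. P53 targets rose in 8 and fell in 6 of 28 cases with palbociclib (adjusted p = 0.985), KMT2A fusion targets rose in 6 and fell in 2 of 24 (0.445), interferon genes rose in 10 of 37 (0.0838), and MAPK and immediate-early genes rose and fell in 5 each of 35 (0.668). FLT3 and STAT5 targets rose in 4 and fell in 2 of 20 (0.564), stress response genes rose in 8 and fell in 13 of 37 (0.668), and BCL2 family genes rose and fell in 2 each of 13 (0.668), all with palbociclib. With YKL-06-102, BCL2 family genes rose in 8 and fell in 2 of 13 cases (median 0.15, camera adjusted p = 0.0971). Interferon genes rose in 11 and fell in 2 of 37 (0.0957), and MAPK and immediate-early genes rose in 9 and fell in 7 of 35 (0.794). Median and mean differed in sign for the MAPK, FLT3 and STAT5, stress and BCL2 lists with palbociclib. The same held for the MAPK and stress lists with YKL-06-102 and for the FLT3 and STAT5 list with BSJ-03-123. With YKL-06-102, the cereblon list (adjusted p = 0.0785), replication-dependent histone genes (0.794) and mitochondrially encoded genes (0.794), a sign of RNA quality, were not called. Of 46 listed histone genes, 23 were found in the table and 13 were tested in these libraries of polyadenylated RNA. The missing call therefore does not show that histone genes stayed unchanged. Lymphoid (0.954), erythroid and megakaryocyte (0.932) and stromal and epithelial markers (0.794) were not called with YKL-06-102 either, by the same camera adjusted p. With BSJ-03-123 and palbociclib the 7 stromal and epithelial markers had medians of 0.23 and 0.19, beside 0.12 and 0.11 for the myeloid list. With each, 2 of the 7 rose and 0 fell, the lowest at 0.056 and 0.062. Camera did not call them (adjusted p = 0.311 and 0.406), while fry, which tests a list without the other genes, did (adjusted p = 0.00124 and 0.00122). With BSJ-03-123 fry also called other lists that camera did not, such as NF-kappaB (0.00137), cholesterol (0.00173), lysosome (0.00247) and cereblon (0.0168). It did not call interferon (0.135) or stress response genes (0.0732). With YKL-06-102 it called cereblon (6.87e-05), NF-kappaB (1.37e-05) and lysosome genes (6.87e-05). Its call thus does not set the stromal and epithelial markers apart. Mitochondrial genes took 3.03 ± 0.534% of counts with DMSO, 2.80 ± 0.252% with BSJ-03-123, 2.96 ± 0.318% with YKL-06-102 and 2.89 ± 0.201% with palbociclib (SD, n = 3).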

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

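The comparisons with a weaker palbociclib response and with a weaker block of the E2F genes, the covariance over all expressed genes, the removal of GC trends, the thinning of libraries and the number of genes given per pair of compounds were chosen only after results were seen. No test of outlying libraries was run in these groups of 3, though DMSO replicate 2 stood farthest from its group.

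Some genes were called in opposite directions by 2 compounds against DMSO and also in the direct contrast, and for each pair the 4 with the largest direct difference are given (edgeR quasi-likelihood test, average log2 CPM of at least 2). CTDSPL fell with BSJ-03-123 (-0.76 ± 0.15) and palbociclib (-1.12 ± 0.16) and rose with YKL-06-102 (1.26 ± 0.12), which made -2.02 ± 0.14 for BSJ-03-123 against YKL-06-102 and 2.38 ± 0.14 for YKL-06-102 against palbociclib. GIMAP1 rose with BSJ-03-123 (0.59 ± 0.13) and fell with YKL-06-102 (-1.07 ± 0.16), a difference of 1.66 ± 0.15, though read-through transcripts of its neighbour GIMAP5 make its counts uncertain. LMO4 (-0.42 ± 0.070 and 0.74 ± 0.060, difference -1.16 ± 0.064) and MAP3K6 (-0.69 ± 0.084 and 0.27 ± 0.072, difference -0.96 ± 0.080) fell with BSJ-03-123 and rose with YKL-06-102. TK2, RARG and UBASH3B fell with YKL-06-102 (-1.78 ± 0.063, -1.54 ± 0.13 and -1.53 ± 0.10) and rose with palbociclib (0.18 ± 0.049, 0.37 ± 0.097 and 0.25 ± 0.078), with differences of -1.97 ± 0.062, -1.91 ± 0.12 and -1.78 ± 0.100. The rise of UBASH3B with palbociclib was lost without DMSO replicate 2 (0.19), without palbociclib replicate 1 (0.21) and with DESeq2 (0.24), while its difference between the compounds was not. In all 85 genes moved in opposite directions with the 2 conjugates and 171 with YKL-06-102 and palbociclib.

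A pattern that stood out was a response to YKL-06-102 that palbociclib did not give. It comprised 117 genes, 86 higher and 31 lower, that changed at least 2-fold with YKL-06-102 against both DMSO and palbociclib, with a log2 fold change within 0.5 of 0 for palbociclib against DMSO. TREM2, PPP1R13L, C11orf95 and TK2 are among them. A weaker dose of the palbociclib response would leave the genes that differ between the compounds nearer to DMSO with YKL-06-102, but 1928 of 3507, or 55.0%, lay farther from it. With the GC trend of each library removed, 100% of the 117 genes stayed called, and their median absolute difference from palbociclib was 1.44 against 1.43. YKL-06-102 libraries were the largest on average, and with all libraries thinned to the smallest total 108 genes, or 92.3%, stayed called, with a median of 1.45 over all of them still tested. Of the 9 others 7 no longer passed the filter on low counts, and the 2 still tested, MAP3K12 and PPP1R12A-AS1, named after their values were seen, had log2 fold changes of -1.18 ± 0.46 and 1.12 ± 0.38 before and -1.18 ± 0.54 and 1.14 ± 0.47 after thinning, so their calls ended with larger errors. Both overlap a gene with more counts and were near the threshold before: the call of MAP3K12 was also lost without any 1 of the 6 libraries (-1.25 to -1.01) and that of PPP1R12A-AS1 without YKL-06-102 replicate 2 (0.99) or palbociclib replicate 3 (0.88). The GC values argue against GC trends as the whole cause. Depth was already scaled in the fit, so thinning could mainly enlarge errors. It shows only that most of these calls did not need the larger libraries.

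Some genes of the pattern, such as TREM2, are known from macrophages, though no macrophage list was tested over the pattern. RNA of macrophages in the YKL-06-102 libraries was therefore tested with 15 abundant macrophage transcripts. This line expressed 5 of them enough to be tested, and 0 were called higher with YKL-06-102. The 15 summed to 12.3 ± 0.827 CPM with YKL-06-102 and 10.6 ± 1.12 CPM with DMSO, where the higher genes of the pattern rose by 864 CPM in sum. The most abundant were APOC1 (6.72 CPM with DMSO and 7.34 with YKL-06-102) and FOLR2 (1.99 and 2.26). Such cells would have brought these transcripts along, which argues against them. An effect of YKL-06-102 itself, the treatment that the design gives, stays as a hypothesis, found and tested on the same libraries. Against DMSO, BSJ-03-123 moved some of these genes the same way: 27 of the 117, or 23.1%, were called in the same direction. The median change was 16.7% of that with YKL-06-102. Over all 14214 tested genes BSJ-03-123 against DMSO called 1763 higher and 2234 lower. Calls of palbociclib against DMSO among the 117 were not counted. Of the 22 genes called for BSJ-03-123 against palbociclib, only ZNF692 and SERPINH1 belong to the pattern. A response shared by the conjugates but not by palbociclib was thus not shown for most of it. The 117 genes were chosen for little change with palbociclib, and the responses to BSJ-03-123 and palbociclib had an r of 0.865 over all genes.

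A further pattern was that both conjugates held some genes higher than palbociclib did. Of the 22 genes higher with BSJ-03-123 than with palbociclib, 18 were also higher with YKL-06-102, and 0 genes were called lower with both, as edgeR called 0 lower with BSJ-03-123 with all 12 libraries, TMM and the filter on low counts (517 at an unadjusted p below 0.05, 5 by DESeq2, and by edgeR 22 with no filter, 14 with 2 groups only and 10 with GC trends removed; the 22 became 3 to 14 in leave-one-out, 3 without palbociclib replicate 1). Of the 22, 11 are members of the E2F and G1/S list, all among the 18, and 18 were called lower with palbociclib than with DMSO. The same palbociclib libraries stand on both sides of this comparison, which alone gives a positive covariance. Over 10368 genes with an average log2 CPM of at least 2, the covariance of the 2 differences was 0.00875, against 0.00186 that the spread between the palbociclib libraries adds. The ratio was 4.70 (95% bootstrap interval over genes 4.28 to 5.14, 1000 draws, where genes are not independent), and 2.94 (2.58 to 3.32) over the 6039 of them not called with palbociclib against DMSO. That argues against the spread between the shared palbociclib libraries as the whole cause. A shift common to all of these libraries would enter both differences without adding to that spread. The ratio therefore cannot tell such a shift apart.

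A weaker block of the E2F genes by both conjugates goes with the values of the 11 E2F members: the order from the lowest was palbociclib, BSJ-03-123, YKL-06-102 in 69 of 72 genes of the whole list. That order was counted after the list differences between compounds were known and largely restates them, so it is no separate support. The same response as with palbociclib but weaker would leave the 7 other genes no higher than DMSO, or than palbociclib where that raised them, yet 4 of them were called higher than both palbociclib and DMSO with 1 or both conjugates, which argues against it as the whole cause of these 4. With YKL-06-102 against DMSO they were IL7R (2.63 ± 0.11), ZNF692 (1.14 ± 0.044), SERPINH1 (1.04 ± 0.034) and TSPAN14 (0.26 ± 0.046), and with BSJ-03-123 IL7R (1.21 ± 0.12) and ZNF692 (0.52 ± 0.045). A weaker response stays open for FADS1, FAM129A and HSPA1A, which lay below DMSO with BSJ-03-123 (-0.49 ± 0.031, -0.23 ± 0.058 and -0.67 ± 0.040) and at 0.055 ± 0.030, -0.39 ± 0.057 and -0.45 ± 0.040 with YKL-06-102. FADS1 passed the test as higher than DMSO with YKL-06-102 without its replicate 3 (0.096) and with library totals (0.092). For BSJ-03-123 against palbociclib, the call of TSPAN14 was lost without any 1 of the 6 libraries (0.20 to 0.25), that of FAM129A without any 1 except BSJ-03-123 replicate 1 and palbociclib replicate 2 (0.31 to 0.33), that of IL7R without BSJ-03-123 replicate 2 or palbociclib replicate 1 or 2 (0.59 to 0.64) and that of SERPINH1 without palbociclib replicate 1 (0.20), while ZNF692 and HSPA1A were called in each of these runs. For YKL-06-102 against palbociclib, FAM129A was lost without YKL-06-102 replicate 2 or palbociclib replicate 1 or 3 (0.16 to 0.19). TSPAN14 and FAM129A were named after their values were seen.

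The 6 libraries of each contrast can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split called 3997 genes for BSJ-03-123 against DMSO, with 1 as the highest of the others. For YKL-06-102 against DMSO it called 5249, for palbociclib against DMSO 4731, for BSJ-03-123 against palbociclib 22, for YKL-06-102 against palbociclib 3507 and for BSJ-03-123 against YKL-06-102 2861, and the highest of the others was 0 each time by edgeR, the 1 tool run on the splits.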

How the results depend on the processing

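The removal of GC trends, the removal of length trends and the thinning of libraries were chosen only after the results were seen.

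Outside BSJ-03-123 against palbociclib, every count of called genes, both directions together, lay within 1.5 times its value under each alternative run. The ranges were 3059 (DESeq2) to 4617 (total counts) for BSJ-03-123 against DMSO, 4312 (DESeq2) to 5583 (without DMSO replicate 2) for YKL-06-102 and 3863 (DESeq2) to 5345 (total counts) for palbociclib. They were 2707 (without palbociclib replicate 1) to 4310 (2 groups only) for YKL-06-102 against palbociclib and 2218 (DESeq2) to 3323 (2 groups only) for BSJ-03-123 against YKL-06-102. Library totals moved the balance of directions: 2852 genes were then higher and 1765 lower with BSJ-03-123, 2877 and 2422 with YKL-06-102 and 3396 and 1949 with palbociclib. Counts of 1 direction moved by over 1.5 times in 4 cases: the higher genes with BSJ-03-123 and with palbociclib under library totals, the lower genes of YKL-06-102 against palbociclib (985 to 1057 without palbociclib replicate 1 or 2 or any 1 YKL-06-102 library, 1103 with DESeq2) and the higher genes of BSJ-03-123 against YKL-06-102 (795 to 903 without BSJ-03-123 replicate 1 or any 1 YKL-06-102 library). The median of all genes moved by less than 0.1 on the log2 scale.

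For BSJ-03-123 against palbociclib the 22 genes became 64 with no low-count filter, 75 with 2 groups only, 43 with DESeq2 and 77 with GC trends removed, each time with all 22 among them and with 22, 14, 5 and 10 lower. Leave-one-out gave 3 (without palbociclib replicate 1) to 14. The count at least 2-fold different went from 0 to 2 with no low-count filter, 1 with 2 groups only and 1 with GC trends removed, and was 0 to 1 in leave-one-out (1 without BSJ-03-123 replicate 1 or palbociclib replicate 3). The cause was not tested.

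The E2F and G1/S list stayed called in every contrast under every alternative run, with medians from -1.53 to -1.47 for palbociclib, -1.41 to -1.36 for BSJ-03-123, -1.02 to -0.97 for YKL-06-102 and 0.11 to 0.13 for BSJ-03-123 against palbociclib. With an estimated correlation, camera no longer called G2/M for BSJ-03-123 against palbociclib (median 0.033, adjusted p = 0.252; fry 0.112), YKL-06-102 against palbociclib (0.14, 0.0612; fry 2.53e-05) and BSJ-03-123 against YKL-06-102 (-0.11, 0.139; fry 2.74e-04), where fry called the last 2. It also no longer called, by the same adjusted p, the CDK-RB module for BSJ-03-123 against palbociclib (0.037, 0.252) and YKL-06-102 (-0.086, 0.0677). Ribosome biogenesis was lost for YKL-06-102 against DMSO (-0.094, 0.0963) and for BSJ-03-123 against palbociclib (0.023, 0.169) and YKL-06-102 (0.042, 0.159). The lysosome (0.078, 0.140) and NF-kappaB (0.17, 0.0733) lists were lost for YKL-06-102 against DMSO, and cholesterol for YKL-06-102 against palbociclib (0.11, 0.0612) and BSJ-03-123 against YKL-06-102 (-0.091, 0.110).

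Single genes changed sign only where they were not called. CCND3 with BSJ-03-123 went from -0.0020 to 0.042 with total counts, 0.010 with no low-count filter, 0.013 with the length trend removed and 0.0073 when thinned, and lay between -0.041 and 0.064 in leave-one-out. MYC with BSJ-03-123 went from -0.018 to 0.026 with total counts and lay between -0.048 and 0.025 in leave-one-out. CDK6 in BSJ-03-123 against YKL-06-102 went from 0.030 to -0.022 and -0.065 with the GC or length trend removed and lay between -0.013 and 0.031 in leave-one-out. CDK6 in YKL-06-102 against palbociclib passed the threshold with the GC (0.084) or length trend removed (0.083). CCND3 passed with YKL-06-102 with total counts (0.12), no low-count filter (0.11) or thinning (0.12), and with palbociclib with GC trends removed (-0.091). MYC with YKL-06-102 was lost with total counts (-0.064), no low-count filter (-0.073), 2 groups only (-0.082) and thinning (-0.083). In BSJ-03-123 against palbociclib, CCNE2 was lost with limma-voom (0.84) and thinning (0.81), as was HELLS (0.44 and 0.42), besides the leave-one-out losses given with that comparison. The cause was not tested.

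Libraries that share a replicate number were on average hardly more alike than others (mean r across genes 0.00700 against -0.00353). Of 18 such pairs 2 had an r over 0.1, both of DMSO with BSJ-03-123 (0.229 and 0.202). The remaining same-number pair of these groups had 0.0864, and their other pairs reached at most 0.0514. In all, 7 libraries correlated best with their own number, so a pairing of DMSO with BSJ-03-123 libraries is not excluded. With the number as a block, 3991 genes were called for BSJ-03-123 against DMSO, where the main fit called 3997. With the number as a block, 25 genes were higher and 1 lower with BSJ-03-123 than with palbociclib, 20 of the 22 among them. On simulated data at these depths, 98% of genes changed 1.5-fold were called in that contrast, and 18 unchanged genes made up 8.53% of all its calls.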

Other observations

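The tests of the heat shock list and the counts of G2/M and E2F genes in order were chosen after the results were seen.

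Among the 22 genes higher with BSJ-03-123 than with palbociclib were 4 heat shock genes, HSPA1A (0.39 ± 0.042), HSPH1 (0.18 ± 0.030), SERPINH1 (0.22 ± 0.036) and DNAJA4 (0.20 ± 0.037), of which the last 3 were singled out after their values were seen. The call of SERPINH1 was lost without palbociclib replicate 1 (0.20), that of HSPH1 without BSJ-03-123 replicate 2 (0.16) or palbociclib replicate 1 (0.18) or 2 (0.18), and that of DNAJA4 without any 1 except BSJ-03-123 replicate 1 (0.17 to 0.21 in the runs that lost it). A list of 21 heat shock genes was then written from general knowledge, and the 17 members apart from these 4 were tested. Their median log2 fold change was 0.051, 16 of 17 were positive, and camera with an estimated correlation gave p = 0.0127, unadjusted, while no member passed the edgeR test alone. The genes may differ as a group, by a small amount. For YKL-06-102 against palbociclib the same 17 had a median of 0.039 (camera with an estimated correlation, p = 0.541), so there the group was not shown to differ, though 4 of the 17 were called higher and 0 lower by edgeR. The 21 heat shock genes together, with the 4 chosen ones among them, gave p = 0.0357 by camera with an estimated correlation, and edgeR called 6 of the 21 higher and 0 lower.

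Against DMSO most heat shock genes fell with every compound. Of the 17 members apart from the 4 above, 16 were called lower with palbociclib, with a median of -0.26 (camera with an estimated correlation, p = 0.0171), 15 with BSJ-03-123, with a median of -0.19 (camera p = 0.0448 with an estimated correlation), and 15 with YKL-06-102, with a median of -0.20 (camera p = 0.0299 with an estimated correlation). SERPINH1, a chaperone of collagen and 1 of the 4, rose with YKL-06-102 (1.04 ± 0.034). These p-values are unadjusted, and the list was written after some of its members had been seen.

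The order palbociclib, BSJ-03-123, YKL-06-102 from the lowest held in 39 of 64 G2/M genes, against 69 of 72 E2F and G1/S genes, and the G2/M list lost its call with an estimated correlation in each comparison between compounds (camera adjusted p = 0.252, 0.0612 and 0.139). The median effect on the G2/M genes was 91.3% of that of palbociclib with BSJ-03-123 and 72.6% with YKL-06-102. All 12 libraries were taken at 6 h and 200 nM, so the data hold no course over dose or time.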
